A study of Mus musculus with 6 samples.

How the data were processed

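Single-nucleus RNA was sequenced from hippocampi of 12-month-old apoE4 knock-in mice, which carry human APOE4 in place of mouse Apoe. Per the labels, 3 mice were given bumetanide, 0.2 mg/kg daily by intraperitoneal injection for 60 days, and 3 were given vehicle. Bumetanide is a loop diuretic that inhibits the chloride importers NKCC2 (Slc12a1) and NKCC1 (Slc12a2). Nuclei were stained with DAPI and sorted with gates against debris and doublets, per the labels' protocols, before droplet capture.

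The deposited matrix holds whole-number UMI counts per gene and nucleus barcode, not normalized. Counts were made with Cell Ranger 2.2.0 on mouse build mm10, per the submitters' processing notes, and the barcodes are those retained by the filtering of the authors. The annotation, whether intronic reads were counted, whether counting used strand, and whether reads were equalised between libraries are not given in the sources used here. The matrix held 31053 genes and 27421 barcodes of 6 libraries. All gene positions are from GENCODE vM21 on GRCm38, the assembly called mm10, and 31011 of the gene identifiers were in that annotation.

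The barcodes carry a library number from 1 to 6, and no sample title or description carries those numbers in a way that matches 1 sample alone. The libraries were therefore not assigned to treatment, and no comparison of bumetanide with vehicle was made. The design text of the series describes human neurons derived from stem cells, while every sample label names mouse hippocampus, and the sample labels were followed. Values are given for each library, or as the median and range over the 6 libraries. The fallback to values per library, the filters, the gene lists, the cell type markers and the rule for named genes were fixed before the data were examined.

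Barcodes with at least 200 genes and under 5% mitochondrial counts were kept, which removed 6 and 17 barcodes. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.06, and the 514 called barcodes (1.88%) were removed. The automatic threshold marked only 1 of 4886 nuclei in library 1, against 0.893% to 4.17% in the other libraries, so calling did not work there. A shared score threshold of 0.25 for every library was added as an alternative after seeing the data. The remaining 26884 nuclei were scaled to 10000 counts and log-transformed. From 2000 highly variable genes, leaving out 356 gene-list genes that are not markers, 30 principal components and 15 neighbours were taken, followed by Leiden clustering at resolution 1 (igraph 0.11.9).

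Of the 26 clusters, 19 were named from 24 marker lists and 7 stayed unnamed. A name needed at least 3 markers of its list at 2-fold or more over the other nuclei and at 20 CPM or more, and a lead of 2 markers over the next list, with 5 CPM added before the fold. A cluster stayed unnamed where another list had more markers among its top 10 genes, or, for glia, where its mean log2 fold was under 0.5 times that of the leading cluster of that name. These thresholds and checks were set after the data were seen. Names carry "-like" because they rest on markers alone. The subicular or cortical excitatory-like clusters of 1293 and 765 nuclei were named from 4 markers each. The mean log2 fold of the whole list was 0.03 and -0.31 there, so the list as a whole was not raised. The named clusters formed 11 classes, of which 7 had at least 20 nuclei in every library and are called well sampled.

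Counts were summed per library and class and divided by the summed total to give CPM, the usual count scaled to depth. A gene was said to be led by a class where that class had the highest median CPM among the 7 well-sampled classes. The number of libraries with that class highest stands beside it. List genes with under 100 counts in these classes, and genes used as markers, were left out of that comparison, and the minimum of 100 was set after the data were seen. Intervals for shares are exact binomial (Clopper-Pearson) and those for counts exact Poisson, at 95%. They cover counting error only, not differences between mice. No correction for free RNA was made. What a source class could add as free RNA was bounded by the lowest ratio, class over source, among its markers at 100 CPM or more there, taken at the upper Poisson limit. This check was chosen after the data were seen.

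CPM by total was set beside CPM scaled with TMM factors from edgeR 4.0.16 in R 4.3.3. The log2 median factor was -0.59 in CA1 pyramidal-like, -0.56 in dentate granule-like and CA3 pyramidal-like, -0.47 in subicular or cortical, -0.37 in inhibitory, -0.18 in oligodendrocyte-like and -0.07 in oligodendrocyte precursor-like nuclei. It was 0.30 in fibroblast-like, 0.69 in astrocyte-like, 0.29 in microglia-like and 1.25 in choroid plexus-like nuclei. TMM scaling therefore raises neuronal levels relative to glial ones, and counts of genes led in all 6 libraries are given under both scalings. For a named gene, the text says where the class with its highest median turned with TMM scaling. In the less sampled classes the factor itself varied between libraries. It was 1.05 to 3.41 in fibroblast-like, 1.29 to 2.16 in astrocyte-like and 1.64 to 3.78 in choroid plexus-like nuclei. These classes held 309222, 115835 and 75992 UMIs in all, against 13568473 in granule-like nuclei. Such factors are uncertain, so a turn that involves these classes does not settle which class is highest.

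The rule for named genes took Slc12a1, Slc12a2, Slc12a5 and Apoe, the 4 members of each of 18 gene lists with the highest median CPM in any class, and the 20 genes with the largest ratio between the highest and the lowest library. That ratio was taken over all retained nuclei, among 3436 genes with at least 50 CPM in the median library. Members that served as cell type markers (Slc4a4, Nr4a2, Rora, Rorb, Apod and Gfap) are not reported as members of those lists. Some genes that the rule took are not reported here. Other genes were named after their values were seen, and the text says so.

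The comparison of classes was tested on simulated data with known answers. Counts were drawn from the CA1 pyramidal-like profile at the real totals of oligodendrocyte-like and CA1 pyramidal-like nuclei for 8454 genes, with 200 genes raised in the first class. Of 100 genes raised 2-fold, 82 were led by that class in all 6 libraries. So were 99 of 100 raised 4-fold and 60 of 8254 unchanged genes (0.727%). Unchanged genes led by CA1 pyramidal-like nuclei were not part of this count. No other class was simulated, while the comparison used for the results runs over all well-sampled classes. The 0.727% is therefore not the rate of false leads in that comparison. The Poisson interval held the true level for 95.3% of the 8454 genes. The counts were themselves drawn as Poisson, so this checks the calculation and says nothing of the spread between mice. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

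Alternatives were a minimum of 500 genes per nucleus, under 1% mitochondrial counts, called doublets kept, Leiden resolutions of 0.5 and 2, another random seed, TMM scaling, each nucleus thinned to 1000 UMIs, and each library left out in turn. The planned tests between treatments were not run.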

Results

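Nuclei were profiled from the hippocampus of apoE4 knock-in mice, a model carrying the human APOE allele linked to late-onset Alzheimer disease, after 60 days of bumetanide (3 mice) or vehicle (3 mice). The study asked what the drug does to hippocampal cells in vivo. The 6 libraries could not be matched to the treated and vehicle mice, so that question is not answered here. Levels are given per library and per cell class, for the transporters the drug acts on, for Apoe and for 18 gene lists.

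The libraries held 9292134, 9881354, 9898064, 8918702, 6285736 and 6461870 UMIs in libraries 1 to 6. After filtering, 4885, 4127, 4328, 4165, 4734 and 4645 nuclei remained, with median counts of 1731, 2146, 2058, 1894, 1156 and 1272 UMIs per nucleus. Libraries 5 and 6 were thus the shallowest. Malat1, a nuclear-retained long noncoding RNA, took 9.05% of all UMIs, and mitochondrial transcripts took 0.0945% to 0.130% per library. Xist, the transcript that coats the inactive X chromosome, lay between 2110 and 2603 CPM in every library, while Ddx3y on the Y chromosome did not exceed 6.86 CPM. Across 3436 genes with at least 50 CPM in the median library, log2 CPM of the 15 pairs of libraries correlated across genes at Pearson r of 0.983 to 0.996, genes not being independent replicates.

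Neurons made up most of the nuclei: 80.9% of the 26884 retained nuclei were in named neuronal classes. Dentate granule-like nuclei were the most frequent class in every library, at a median of 33.5% (32.0% to 35.3% over the 6 libraries). Subicular or cortical excitatory-like nuclei took 15.3% (11.9% to 19.1%), CA1 pyramidal-like nuclei 15.2% (14.0% to 18.8%), CA3 pyramidal-like nuclei 8.58% (4.33% to 9.00%) and inhibitory neuron-like nuclei 8.02% (6.78% to 10.6%). The lowest CA3 pyramidal-like share, 4.33% (exact 95% interval 3.77% to 4.95%), was that of library 5.

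Oligodendrocyte-like nuclei, the myelinating glia, took a median of 5.76%. Their share was 12.0% (11.0% to 12.9%) in library 5 and 8.31% (7.53% to 9.14%) in library 6, against 4.23% to 5.98% in libraries 1 to 4. Oligodendrocyte precursor-like nuclei took 2.40% (1.80% to 2.68%). Fibroblast-like nuclei of the leptomeninges ranged widely, from 0.144% (0.0529% to 0.313%) in library 4 to 2.45% (2.03% to 2.94%) in library 6. Astrocyte-like nuclei (0.497%), microglia-like nuclei (0.434%) and choroid plexus epithelial-like nuclei (0.205%) were rare, with 149, 116 and 65 nuclei in all. A further 7.19% of nuclei (6.03% to 8.81%) lay in clusters without a name. Sorting on DAPI and the differing depth can set these shares. With a minimum of 500 genes per nucleus the median oligodendrocyte-like share was 3.20%, the fibroblast-like share 0.705% and the unnamed share 4.17%, and astrocyte-like and microglia-like nuclei were not named.

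**Figure D1:**
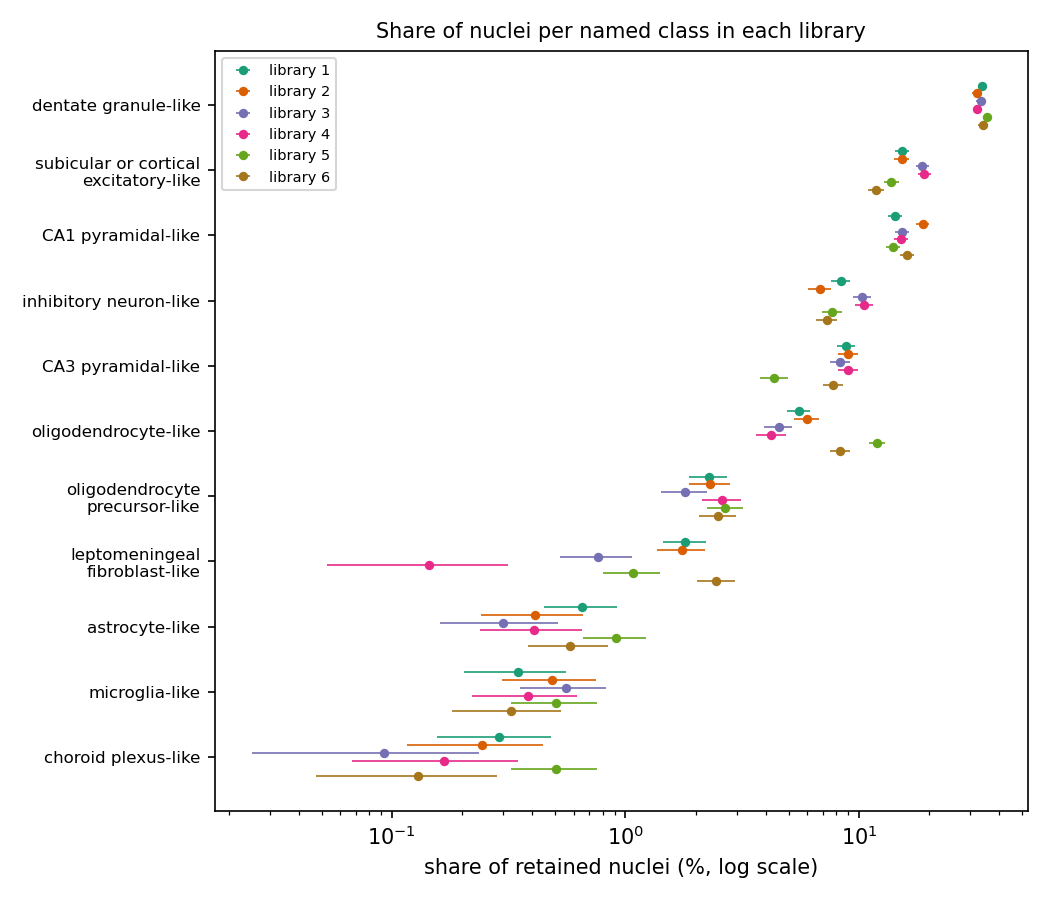
Share of retained nuclei (%, log axis) in each of the 11 named classes, with 1 point per library and bars for the exact 95% binomial interval. Library 5 lies apart for oligodendrocyte-like (12.0%) and CA3 pyramidal-like nuclei (4.33%), and library 4 for fibroblast-like nuclei (0.144%).

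Slc12a2 (ENSMUSG00000024597, chromosome 18, 57878678 to 57946821, plus strand) encodes NKCC1, the chloride importer that bumetanide blocks in the brain. Its highest level in the 7 well-sampled classes was in oligodendrocyte-like nuclei, at a median of 422 CPM (344 to 482 over the 6 libraries; 415 CPM over 455 pooled counts, 95% interval 378 to 455). The next class, inhibitory neuron-like nuclei, had 32.6 CPM (27.0 to 46.0), so oligodendrocyte-like nuclei were 12.9-fold higher, in 6 of 6 libraries under both scalings. CA1 pyramidal-like nuclei had the lowest level, 14.8 CPM (11.3 to 18.0). Oligodendrocyte-like nuclei gave 24.4% of the 1862 Slc12a2 counts with 2.22% of all UMIs. Among the less sampled classes, choroid plexus-like nuclei had 449 CPM (209 to 708, 37 counts), the highest median of any class. With TMM scaling they had 201 CPM (55.3 to 400), below the 478 CPM (401 to 561) of oligodendrocyte-like nuclei. The TMM factor of choroid plexus-like nuclei ranged from 1.64 to 3.78 between libraries, so which class is higher stays open. Fibroblast-like nuclei had 269 CPM (91.9 to 957, 81 counts), and astrocyte-like nuclei 1 count.

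Slc12a5 (ENSMUSG00000017740, chromosome 2, 164960802 to 164999731, plus strand), which encodes the neuronal chloride exporter KCC2, had the opposite distribution. Its median was 102 CPM (93.5 to 116) in subicular or cortical nuclei, the highest in 5 of 6 libraries, and in 4 with TMM scaling. It was 94.5 (70.0 to 105) in CA1 pyramidal-like, 91.6 (70.4 to 104) in granule-like, 74.1 (61.4 to 95.2) in inhibitory and 63.4 (57.4 to 78.3) in CA3 pyramidal-like nuclei, against 16.7 CPM in oligodendrocyte-like nuclei (18 counts), or 44.1 CPM with a minimum of 500 genes per nucleus. The ratio of pooled Slc12a2 to Slc12a5 counts was lowest in CA1 pyramidal-like nuclei, at 0.160 (exact 95% interval 0.132 to 0.192). It was 0.296 (0.258 to 0.338) in subicular or cortical, 0.305 (0.270 to 0.343) in granule-like, 0.407 (0.338 to 0.488) in CA3 pyramidal-like and 0.447 (0.369 to 0.539) in inhibitory nuclei, and 25.3 (15.8 to 43.0) in oligodendrocyte-like nuclei. Over the 6 libraries the ratio ranged more widely. It was 0.135 to 0.207 in CA1 pyramidal-like, 0.188 to 0.338 in subicular or cortical and 0.226 to 0.362 in granule-like nuclei. In CA3 pyramidal-like nuclei it was 0.138 to 0.588, and in inhibitory nuclei 0.314 to 0.628. The ranges of CA3 pyramidal-like and subicular or cortical nuclei thus overlap that of CA1 pyramidal-like nuclei. Within each library, however, CA1 pyramidal-like nuclei had the lowest ratio of the neuronal classes. In library 5 CA3 pyramidal-like nuclei were nearly equal to them, on 4 Slc12a2 and 29 Slc12a5 counts. The ratio does not depend on the scaling of a class. Free RNA can enter it. From the neuronal marker Camk2a, free RNA of neuronal composition could give oligodendrocyte-like nuclei up to 12.3 CPM of Slc12a5, within the interval of the pooled 16.4 CPM (9.74 to 26.0), so that level is not distinguishable from background. From the oligodendrocyte marker Prr5l, free RNA of the composition of oligodendrocyte-like nuclei could give neuronal classes at most 1.14 to 2.64 CPM of Slc12a2, below their pooled 14.5 to 33.2 CPM. Free RNA of other composition was not bounded.

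Slc12a1 (ENSMUSG00000027202, chromosome 2, 125152505 to 125230002, plus strand), the renal NKCC2, was close to the limit of detection, with 62 counts in all well-sampled classes together. Its highest median was 2.07 CPM, in CA1 pyramidal-like nuclei. No count fell in oligodendrocyte-like nuclei, where up to 3.37 CPM would be compatible with a count of 0. For Slc12a2, a minimum of 500 genes per nucleus lowered the oligodendrocyte-like median to 147 CPM. That class then held 774 nuclei, of which 357 were oligodendrocyte-like at the minimum of 200, 286 had been unnamed and 107 had been called doublets.

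**Figure D2:**
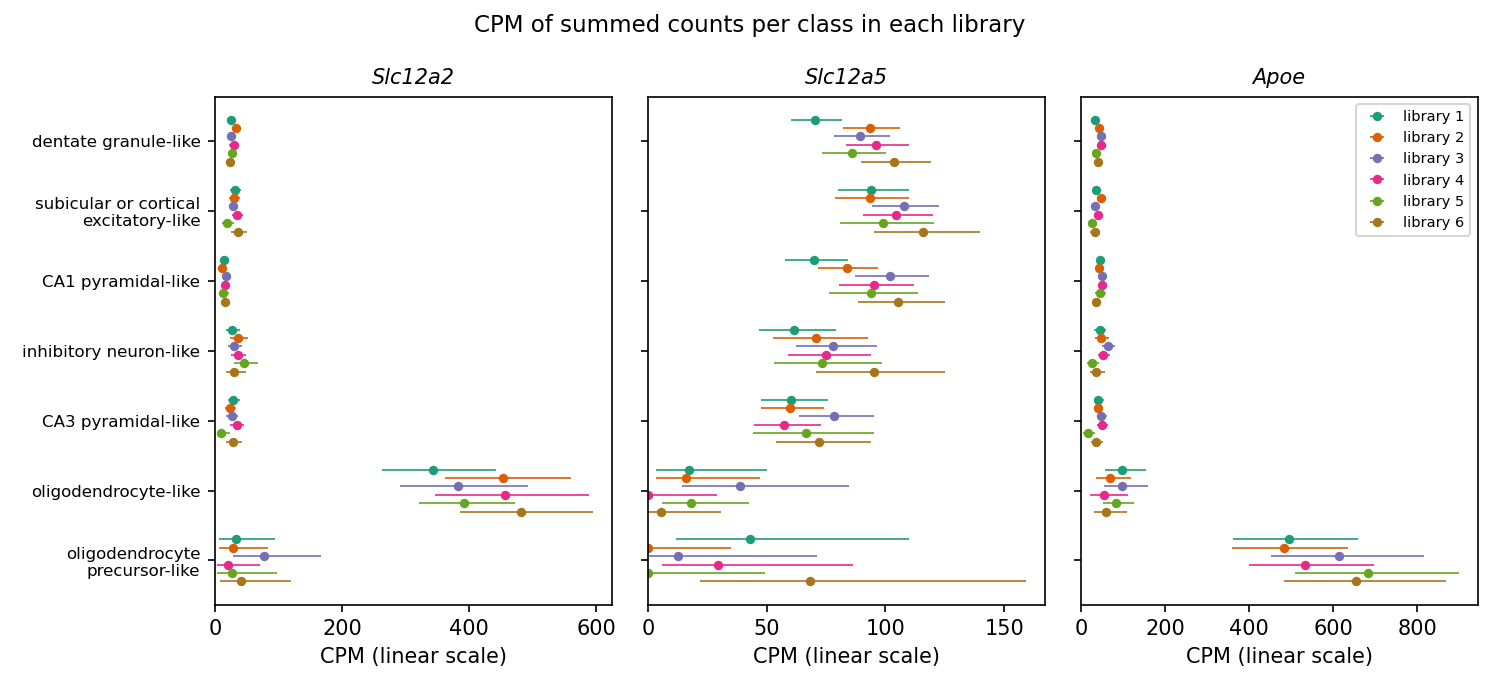
Slc12a2, Slc12a5 and Apoe in CPM (linear axis) in the 7 well-sampled classes, with 1 point per library and bars for the exact 95% Poisson interval of its count. Slc12a2 in oligodendrocyte-like nuclei (344 to 482 CPM) and Apoe in oligodendrocyte precursor-like nuclei (483 to 683 CPM) lie above every other class shown in all 6 libraries.

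Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, minus strand), the lipid carrier of the brain, was highest in astrocyte-like nuclei, at a median of 1319 CPM (628 to 1786, 135 counts). Among well-sampled classes it was led by oligodendrocyte precursor-like nuclei, at 574 CPM (483 to 683; pooled 566, 95% interval 504 to 635). That was 7.44-fold above oligodendrocyte-like nuclei at 77.1 CPM (55.0 to 97.4), and precursor-like nuclei led in 6 of 6 libraries under both scalings. Neuronal classes had 35.9 to 46.2 CPM. How much of these low levels free RNA gives was not tested for Apoe. With TMM scaling the astrocyte-like median was 741 CPM. The gene model is that of the mouse, the mice carry human APOE4, and how much of the human transcript it counts was not tested.

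Of 294 list genes with enough counts, 110 (37.4%) were led by a single well-sampled class in all 6 libraries, and 99 of these were led by the same class in all 6 libraries with TMM scaling too. Oligodendrocyte-like nuclei led 32 of the 110 genes, granule-like nuclei 20, inhibitory nuclei 16, oligodendrocyte precursor-like nuclei 14, CA1 pyramidal-like and CA3 pyramidal-like nuclei 11 each, and subicular or cortical nuclei 6. With TMM scaling 27, 20, 13, 11, 11, 11 and 6 of these remained. When each nucleus was thinned to 1000 UMIs, 42 genes were led in all 6 libraries, only 44 of 1841 oligodendrocyte-like and 112 of 635 oligodendrocyte precursor-like nuclei being deep enough to enter. With a minimum of 500 genes per nucleus, 83 genes were led in all 6 libraries. The count then fell from 4 to 2 for immediate early genes, from 2 to 0 for ribosomal proteins, from 3 to 0 for heat shock genes, from 5 to 3 for activated microglia genes, from 2 to 1 for reactive astrocyte genes, from 2 to 0 for interferon genes and from 4 to 2 for osmotic response genes.

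Of 21 compared genes of chloride transport, 6 were led by 1 class in all 6 libraries, 4 of them by oligodendrocyte-like nuclei. With TMM scaling 5 of the 6 remained. Car2, the carbonic anhydrase that supplies bicarbonate, was at 877 CPM (809 to 1052) in oligodendrocyte-like nuclei, 24.6-fold above the next class, and at 332 CPM with a minimum of 500 genes per nucleus. Wnk1, a kinase that activates NKCC1 through its partner kinases, was at 502 CPM (434 to 794) there, 1.99-fold above precursor-like nuclei; it was named after its values were seen. Stk39, the SPAK kinase downstream of Wnk1, was highest in choroid plexus-like nuclei (2411 CPM, 1297 to 2968). With TMM scaling it was at 902 CPM there and highest in fibroblast-like nuclei (1343 CPM), and its lead in oligodendrocyte-like over granule-like nuclei (240 against 191 CPM) turned with TMM scaling. Slc4a10, a sodium-driven bicarbonate transporter, was at 2134 CPM (766 to 3575) in fibroblast-like nuclei and at 384 CPM (375 to 441) in subicular or cortical nuclei.

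Of 19 compared genes of GABA receptors and GABA handling, 11 were led by 1 class in all 6 libraries (9 also with TMM scaling), 5 by granule-like and 4 by inhibitory nuclei. Gabrg3 was at 2246 CPM (1971 to 2594) in inhibitory nuclei, 3.13-fold above the next class. Among genes named after their values were seen, Gabra4 and Gabrd, subunits of extrasynaptic receptors, were led by granule-like nuclei at 289 CPM (261 to 348) and 50.4 CPM (31.4 to 65.0). Gabra5, another such subunit, was led by CA3 pyramidal-like nuclei at 212 CPM (182 to 230). Gabrb1 (3372 CPM, 2968 to 4124) and Gphn (1408 CPM, 1137 to 1709), the latter the scaffold of inhibitory synapses, were highest in astrocyte-like nuclei, where 396 and 167 counts were summed. With TMM scaling Gabrb1 was at 2245 CPM and still highest there, while Gphn was at 793 CPM and highest in oligodendrocyte-like nuclei (1324 CPM).

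Of 21 glutamate receptor genes, 16 were led by 1 class in all 6 libraries and 15 of these also with TMM scaling. CA1 pyramidal-like nuclei led Grm5 (3245 CPM, 3079 to 3402), Grin2a (3161 CPM, 2995 to 3536) and Gria1 (3127 CPM, 2915 to 3371), each 1.18-fold to 1.23-fold above the next class, with Grm5 at 4884 CPM with TMM scaling. Named after their values were seen, the kainate receptor genes Grik1 and Grik4 were at 1808 CPM (1405 to 2092) in inhibitory and 815 CPM (774 to 934) in CA3 pyramidal-like nuclei. The metabotropic receptor gene Grm3 was at 1572 CPM (1463 to 1712) in oligodendrocyte-like nuclei, 5.45-fold above the next class.

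Of 27 voltage-gated channel genes, 17 were led by 1 class in all 6 libraries (15 also with TMM scaling). Kcnq5, an M-current potassium channel, was at 3567 CPM (3200 to 4634) in CA3 pyramidal-like nuclei, 2.51-fold above the next class, and at 92.2 CPM in granule-like nuclei. Kcnc2, a channel of fast-spiking cells, was at 1838 CPM (1734 to 2320) in inhibitory nuclei, 3.47-fold above the next class. Kcnd2 was nearly equal in CA1 pyramidal-like (3941 CPM, 3807 to 4121) and oligodendrocyte precursor-like nuclei (3920 CPM), the former being highest in 2 of 6 libraries and with TMM scaling in 6. Kcnma1 was nearly equal in subicular or cortical (1890 CPM, 1834 to 2077) and CA3 pyramidal-like nuclei (1861 CPM), the latter being higher with TMM scaling.

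Axon guidance genes gave 16 of 25 led by 1 class in all 6 libraries, all 16 also with TMM scaling. The ephrin receptor gene Epha6 was at 5474 CPM (5232 to 5901) in CA1 pyramidal-like nuclei, 1.58-fold above CA3 pyramidal-like nuclei. The netrin receptor genes Dcc (2375 CPM, 2094 to 2524) and Unc5c (1892 CPM, 1573 to 1976) were highest in CA3 pyramidal-like nuclei, in 6 and 4 of 6 libraries, and the slit receptor gene Robo1 (1736 CPM, 1484 to 1892) in inhibitory nuclei. Immediate early genes, which follow neuronal activity, gave 4 of 16, all 4 also with TMM scaling, among them Homer1 and Nr4a1. Homer1 was at 327 CPM (308 to 351) in CA1 pyramidal-like nuclei, Nr4a1 at 76.6 CPM (61.7 to 97.9) in subicular or cortical nuclei and Nr4a3 at 56.5 CPM (37.1 to 68.7) in CA3 pyramidal-like nuclei, highest there in 5 of 6 libraries. Of 15 clock genes, 1 passed, against 3 at Leiden resolution 0.5 and 2 each with another random seed and with TMM scaling. It was Npas2, at 268 CPM (245 to 336) in subicular or cortical nuclei, 1.80-fold above the next class. Tef was at 240 CPM (92.3 to 285) in fibroblast-like nuclei.

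Of 19 compared genes linked to Alzheimer disease, 11 were led by 1 class in all 6 libraries under both scalings, 6 of them by oligodendrocyte-like nuclei. Mapt, which encodes tau, was at 1472 CPM (1391 to 1642) in oligodendrocyte-like nuclei, 3.35-fold above CA3 pyramidal-like nuclei. App, the amyloid precursor gene, was at 1169 CPM (1094 to 1298) there, 2.16-fold above inhibitory nuclei. Named after their values were seen, Bin1 (547 CPM, 475 to 652), Picalm (313 CPM, 261 to 432) and Adamts4 (134 CPM, 111 to 181) were led by the same nuclei. Clu, a secreted chaperone, was highest in astrocyte-like nuclei at 1048 CPM (628 to 1237), and at 584 CPM with TMM scaling. With a minimum of 500 genes per nucleus the oligodendrocyte-like medians of Mapt and App were 738 and 715 CPM. These levels are shares of the UMIs of a class, so a higher level need not be a higher count per nucleus. The median was 574 UMIs per nucleus in oligodendrocyte-like, 2827 in CA3 pyramidal-like and 1969 in inhibitory nuclei.

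Of 22 cholesterol and lipid genes, 9 were led by 1 class in all 6 libraries under both scalings, 4 by oligodendrocyte-like and 3 by oligodendrocyte precursor-like nuclei. Astrocyte-like nuclei, not well sampled, were outside that comparison. Their summed level of this list was the highest of any class by total, at 4029 CPM (2231 to 4498). It was 1603 CPM (1298 to 1746) in precursor-like and 1315 CPM (1077 to 1658) in oligodendrocyte-like nuclei. The desaturase gene Scd2 was at 356 CPM (267 to 443) in oligodendrocyte-like nuclei, and at 171 CPM with a minimum of 500 genes per nucleus. Of 15 genes of stress-associated oligodendrocytes, a list defined for that cell type, 9 passed under both scalings, 7 in oligodendrocyte-like nuclei. Neat1, the scaffold RNA of paraspeckles, was at 4199 CPM (3883 to 4463), 41.8-fold above the next class, and at 1454 CPM with a minimum of 500 genes. Il33, an alarmin named after its values were seen, was at 449 CPM (395 to 600), 32.5-fold above. Ptgds, the prostaglandin D synthase gene, was highest in fibroblast-like nuclei (2444 CPM, 1231 to 6618), and Ifi27 in choroid plexus-like nuclei (666 CPM, 375 to 1297). With TMM scaling they were at 1529 and 361 CPM, still highest there.

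Few immune genes could be compared. Microglia-like and astrocyte-like nuclei are not well sampled, so they could not lead any gene of the lists below. Of 10 compared genes of activated microglia, 5 were led by 1 class in all 6 libraries, 3 by oligodendrocyte precursor-like nuclei, among them the tetraspanin gene Cd9 at 277 CPM (237 to 426). The summed level of this list was 1949 CPM (976 to 2473) in astrocyte-like, 1244 CPM (1037 to 1393) in precursor-like and 789 CPM (409 to 1360) in microglia-like nuclei. Cd63 was highest in astrocyte-like nuclei at 143 CPM (34.9 to 368; 89.9 with TMM scaling), and B2m in microglia-like nuclei at 112 CPM (0 to 175, 19 counts). Microglia-like nuclei also carried neuronal RNA. Their summed glutamate receptor genes were at 14717 CPM against 15876 CPM in subicular or cortical nuclei, and their voltage-gated channel genes at 10953 CPM against 12551 CPM in granule-like nuclei, so levels in this class are not those of microglia alone. Of 4 reactive astrocyte genes, 2 passed: the complement gene C4b at 193 CPM (155 to 439; 71.2 with a minimum of 500 genes) in oligodendrocyte-like nuclei, and Cp, the ferroxidase ceruloplasmin, at 119 CPM in precursor-like and 280 CPM (140 to 490; 154 with a minimum of 500 genes) in fibroblast-like nuclei. Id3 was at 217 CPM (107 to 272) in choroid plexus-like nuclei, but with TMM scaling was at 74.9 CPM there and at 113 CPM in fibroblast-like nuclei. Of 6 interferon and antigen presentation genes, 2 passed, the histocompatibility genes H2-D1 and H2-K1 in precursor-like nuclei. The 5 activated microglia, 2 reactive astrocyte and 2 interferon genes that passed also did so with TMM scaling. H2-D1 was at 147 CPM (70.5 to 246) in microglia-like nuclei, and Oasl2 at 138 CPM (61.6 to 383) in fibroblast-like nuclei.

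Of 16 osmotic and steroid response genes, 4 were led by 1 class in all 6 libraries, 3 of them also with TMM scaling. The mineralocorticoid receptor gene Nr3c2 was at 1128 CPM (574 to 1170), the steroid-induced Fkbp5 at 1075 CPM (766 to 1709) and the tonicity factor Nfat5 at 735 CPM (581 to 827) in fibroblast-like nuclei. Nr3c2 was at 941 CPM in CA1 pyramidal-like nuclei, and with TMM scaling was highest there, at 1408 CPM against 924 CPM in fibroblast-like nuclei. Tsc22d3, a glucocorticoid-induced gene named after its values were seen, was at 191 CPM (165 to 261) in oligodendrocyte-like nuclei, 33.7-fold above the next class.

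None of 22 nuclear-encoded oxidative phosphorylation genes and none of 11 mitochondrially encoded genes was led by 1 class in all 6 libraries. Ndufs4 (367 CPM, 118 to 626), Atp5a1 (172 CPM), Atp5b (170 CPM) and Uqcrc1 (151 CPM) were highest in choroid plexus-like nuclei, on 9 to 27 counts. With TMM scaling these were at 168, 66.7, 91.2 and 53.1 CPM there, below Ndufs4 in granule-like nuclei (213 CPM) and the other 3 in inhibitory nuclei (127, 102 and 115 CPM). The summed level of the 13 mitochondrially encoded genes differed between the well-sampled classes, from a median of 714 CPM (568 to 986) in CA3 pyramidal-like nuclei to 2100 CPM (1659 to 2665) in inhibitory and 2413 CPM (1847 to 4238) in oligodendrocyte precursor-like nuclei. The mitochondrial transcripts mt-Co3 (1228 CPM), mt-Atp6 (1091 CPM), mt-Cytb (1059 CPM) and mt-Co1 (660 CPM) were highest in fibroblast-like nuclei, and there were at 388, 356, 334 and 278 CPM when nuclei with 1% or more mitochondrial counts were left out. Under that setting 2 mitochondrially encoded genes were led by 1 class in all 6 libraries, as was 1 with called doublets kept and 1 with TMM scaling. Of 21 ribosomal protein genes, Rplp1 and Rps24 were led in all 6 libraries, and neither with TMM scaling. The count was 1 with called doublets kept, with the shared doublet threshold and at Leiden resolution 0.5. Rpl41 was at 211 CPM in choroid plexus-like nuclei, and Rpl6 and Rps6 at 85.5 and 83.5 CPM in microglia-like nuclei, on 17 and 11 counts. With TMM scaling Rpl41 was at 76.5 CPM there and highest in oligodendrocyte-like nuclei (104 CPM), and Rpl6 was highest in granule-like nuclei (109.6 against 69.9 CPM). Ribosomal protein genes have many pseudogene copies, so these counts are uncertain. Of 17 heat shock genes, 3 passed, and 1 also with TMM scaling; 1 passed without nuclei at 1% or more mitochondrial counts. Hspa8 was at 254 CPM in choroid plexus-like nuclei, but with TMM scaling was at 93.3 CPM there and highest in oligodendrocyte-like nuclei (204 CPM). The endoplasmic reticulum genes Hspa5 (203 CPM; 129 with TMM scaling), Hsp90b1 (180 CPM) and Herpud1 (173 CPM) were highest in fibroblast-like nuclei.

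Between libraries, Gm15594 (ENSMUSG00000084947, chromosome 6, 18424684 to 18427885, plus strand), an antisense transcript within Cttnbp2, had the largest ratio of the highest to the lowest library among the 3436 genes, 27.0-fold. It was at 15.0 CPM in library 1 and 15.9 CPM in library 5, and at 404, 334, 356 and 393 CPM in libraries 2, 3, 4 and 6. Use of strand in counting is not given in the sources used here, so its counts are uncertain. The next genes were Ptgds (3.99-fold, 32.9 CPM in library 4 to 131 CPM in library 6) and Ttr, the transthyretin gene and a choroid plexus marker (79.0 CPM in library 3 to 277 CPM in library 2). In granule-like nuclei, which should lack it, Ttr was at 177, 163, 72.2, 105, 167 and 67.4 CPM in libraries 1 to 6, so background counts enter its difference between libraries.

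Neat1 (2.59-fold, 102 CPM in library 4 to 265 CPM in library 5) was highest in library 5, which had the largest share of oligodendrocyte-like nuclei. So were Prr5l (2.88-fold), Apod (2.76-fold) and Enpp2 (2.30-fold), which stand in the marker lists of the oligodendrocyte, fibroblast and choroid plexus classes. Apod was itself highest in oligodendrocyte-like nuclei, at 1734 CPM (1593 to 1927), or 562 CPM with a minimum of 500 genes per nucleus. Zfhx3 (2.72-fold) was lowest in library 4, at 28.7 CPM. On chromosome 6 with Gm15594, the metalloproteinase inhibitor gene Timp4 (115241892 to 115252205, minus strand) was at 41.7 CPM in library 1 and 33.3 CPM in library 5, against 67.2 to 78.5 CPM in the others. Tia1, a stress granule gene (86404219 to 86433405, plus strand), was at 177 and 159 CPM in those libraries, against 78.2 to 83.0 CPM in the others. Genes that differed by 2.01-fold to 2.97-fold included Gm12027, AY036118, Majin, Xlr5a, Pdzrn4, Eps15l1, Gm13944, 6530403H02Rik and Rnf220. Gm13944 is also annotated as antisense and is uncertain for the same reason.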

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

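All alternatives but the shared doublet threshold of 0.25 were chosen before the data were examined. No comparison between treatments was possible, so the planned edgeR, DESeq2, camera and fry tests with their alternatives were not run. No paired analysis was possible because the libraries could not be matched to the replicate numbers in the labels. The median share without 1 library lies within the range of the 6 by construction, so it says nothing of stability. It was 0.764 to 1.24 times the full median over the 12 class shares. Astrocyte-like and microglia-like nuclei were not named with a minimum of 500 genes, nor fibroblast-like nuclei at resolution 2, so these gave no value. Where a cause is not stated below, the cause was not tested.

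A minimum of 500 genes gave 10 named classes, with medians of 35.1% granule-like, 19.3% CA1 pyramidal-like, 1.70% oligodendrocyte precursor-like and 4.17% unnamed nuclei, and Slc12a2 at 147 CPM in oligodendrocyte-like nuclei. Under 1% mitochondrial counts gave 17.8% CA1 pyramidal-like and 4.81% unnamed nuclei, with Slc12a2 at 347 CPM. With called doublets kept, 17.0% of nuclei were CA1 pyramidal-like and 0.327% microglia-like, with Slc12a2 at 329 CPM. The threshold of 0.25 gave 12 classes and 18.2% CA1 pyramidal-like nuclei. Leiden resolution 0.5 gave 12 classes, 11.4% subicular or cortical and 9.05% unnamed nuclei, with Slc12a2 at 349 CPM. Nuclei unnamed at the main settings entered the oligodendrocyte-like class here (137), under 1% mitochondrial counts (135) and with called doublets kept (136). Called doublets entered it too, 23 under 1% mitochondrial counts and 67 with called doublets kept. These lower Slc12a2 levels are thus those of a changed class. Resolution 2 gave 12 classes, 6.33% CA3 pyramidal-like and 10.4% unnamed nuclei. Another seed gave 12 classes and 10.9% unnamed nuclei. TMM scaling gave Slc12a2 at 478 CPM in oligodendrocyte-like and Slc12a5 at 139 CPM in CA1 pyramidal-like nuclei, by its factors below 1 in these classes. Thinning to 1000 UMIs left 42 list genes led by 1 class in all 6 libraries, with fewer nuclei, against 110 without and 83 to 118 under the other settings. Of 95 CPM values, 53 moved beyond their spread with TMM scaling, as did 15 of 80 with a minimum of 500 genes and 22 of 85 when thinned. Depth limits the glia most, at a median of 574 UMIs in oligodendrocyte-like nuclei.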

Other observations

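All tests below were chosen after the result was seen, except the UMI floor for library 5 and the summed counts of Gm15594 and Cttnbp2 in dentate granule-like nuclei. The genes in the next paragraph were also picked after their values were seen.

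Dentate granule-like nuclei held genes whose levels differed between libraries well beyond counting error. Nrg1 (chromosome 8, 31814551 to 32884029), a growth factor gene of the neuregulin family, was at 1415 CPM (95% interval 1369 to 1462) in library 1 and 1379 CPM (1326 to 1433) in library 5. It was at 403, 466, 463 and 469 CPM in libraries 2, 3, 4 and 6, so the values fell into separate clusters. The class joined 3 clusters, which held 648, 673 and 329 nuclei in library 1 and 450, 842 and 378 in library 5. Within each of them Nrg1 was higher in libraries 1 and 5 than in the others, at 1165 CPM or more against at most 441, 1894 against 903, and 730 against 184. In CA1 pyramidal-like nuclei Nrg1 was at 619, 426, 513, 558, 581 and 500 CPM in libraries 1 to 6. Leprotl1 (chromosome 8, 34135572 to 34147033) was at 6.36, 23.8, 31.8, 30.1, 7.47 and 23.4 CPM in granule-like nuclei, low in the same libraries. Slc15a2, a peptide transporter gene, was at 21.1 and 14.7 CPM in libraries 1 and 2, and at 60.3 CPM or more in each of the others. In the first of the 3 clusters it was at 11.3 CPM in library 1 and 28.7 CPM in library 5, with overlapping intervals.

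In oligodendrocyte-like nuclei the complement gene C4b was at 321 (242 to 416), 205, 181, 173, 439 (364 to 525) and 155 CPM in libraries 1 to 6. A subicular or cortical excitatory-like cluster with Cux2 and Angpt1 among its top genes held 142, 16, 223, 137, 154 and 93 nuclei. It was named from 4 markers, and the mean log2 fold of their whole list was -0.31, so that name is uncertain. An unnamed cluster of 34 nuclei with Tac2, Chrna3 and Syt6 among its top genes held 2, 8, 0, 21, 0 and 3.

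The oligodendrocyte-like share was 12.0% in library 5 and 8.31% in library 6 against at most 5.98% in libraries 1 to 4, and these 2 libraries were the shallowest. With a floor at 0.5 times each library's own granule-like median UMI count, library 6 had 0.872% oligodendrocyte-like nuclei, within the 0.718% to 1.00% of libraries 1 to 4, so a lower UMI minimum of the shallower library is a candidate explanation there. Library 5 kept 2.80% (2.31% to 3.36%), above that range, which argues against that minimum as its whole cause. Fewer neuronal nuclei would raise all glia alike, and above that floor the 4.71 oligodendrocyte-like nuclei per astrocyte-like nucleus of library 5 (3.01 to 7.65) lay within the 2.25 to 6.5 of libraries 1 to 4, but its 1.71 per precursor-like nucleus (1.25 to 2.36) lay above their 0.485 to 0.812 (0.519 to 1.27 for the highest) and the 0.636 of library 6, and its precursor-like share of 1.63% within their 1.19% to 1.70%, which argues against it as the whole cause in library 5. Treatment stays open, since the libraries could not be assigned to it, and no biological explanation was tested.

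The fibroblast-like share and that of an unnamed cluster of 694 nuclei with Zic1 and Prkcd, genes of thalamic neurons, had the same order over the 6 libraries, the latter being 3.25%, 3.15%, 1.85%, 0.696%, 2.56% and 3.77%. Tissue next to the hippocampus carried over in dissection may bring both, and Spearman rho was 1 (exact permutation p = 0.00278, adjusted p = 0.451 over 325 pairs of clusters) and Pearson r 0.977 (exact p = 0.00139; 0.978 without libraries 4 and 6). With 6 libraries the exact p of rho cannot go below 0.00278, which 19 of the 325 pairs would have to reach to pass the adjustment, and 2 reached a rho of 1, so this test could not have supported the relation and leaves it open. The unnamed cluster gave 634 of the 690 nuclei named thalamic neuron-like with a minimum of 500 genes and 691 of 782 at Leiden resolution 0.5, while 58 of its nuclei were named Cajal-Retzius-like at resolution 2. Depth is argued against, since its share differed 4.67-fold among libraries 1 to 4, of similar depth, and 1.76-fold without library 4 (intervals above 2.78% and below 2.30%). Unnamed clusters of 91 and 34 nuclei also had thalamic neuron as their best marker list. Their rho was 0.6 and -0.058 with each of the 2 shares above, so not every such cluster followed the fibroblast-like share. No biological explanation was tested.

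Gm15594 was near 0 in libraries 1 and 5 alone, and within granule-like nuclei the highest library was 28.3-fold above the lowest, which argues against a mix of cell classes. Counts given to Cttnbp2 on the other strand could account for part in inhibitory and granule-like nuclei, where the sum of both genes differed 1.19-fold and 1.23-fold between libraries and Cttnbp2 in the low libraries exceeded the highest of the others by 88.4 CPM against 157 CPM missing and by 119 CPM (upper bound 227) against 366 CPM missing. In CA1 pyramidal-like, CA3 pyramidal-like and subicular or cortical nuclei the sum differed 1.41-fold, 1.58-fold and 1.42-fold, and the upper bounds of that excess were 59.9, 40.0 and 29.3 CPM against 477, 217 and 293 CPM missing, which argues against it there. An inherited stretch of DNA that differs between the mice may lower it. Of the 50 genes with the largest ratio in granule-like nuclei, 3 lay on chromosome 6 against 2.22 by chance (permutation p = 0.380 over 10000 shuffles). That ratio takes the highest and lowest library whichever they are, and the count covers the whole chromosome. It therefore does not ask whether genes near Gm15594 differ in libraries 1 and 5, and leaves the explanation open. A treatment that acted alike in its 3 mice is argued against, since every way to part the 6 libraries 3 and 3 left a part whose highest library was at least 22.1-fold above its lowest in granule-like nuclei, while a treatment that acted in 2 of its 3 mice stays open.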
